A study of Homo sapiens with 7 samples.

How the data were processed

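ChIP-seq libraries were made from BJAB cells with antibodies to Pol II, SPT5, TRIM28, OGA and O-GlcNAc and with mouse and rabbit IgG. Per the labels' protocols, cells were fixed in 1% formaldehyde for 5 min, sonicated and precipitated with 10 µg of antibody, and libraries were built from 25 ng of DNA. Each of the 7 libraries was 1 group of 1 sample, taken from the sample titles. The 5 peak lists of the specific antibodies were used, and the 2 IgG libraries were not analysed here. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.30 and Bowtie2 2.1.0 were used and the build was hg19. The peak caller, its version, its control library and its threshold are not given in the sources used here.

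The deposited files hold 1 line per peak in the narrowPeak layout. The authors' fold enrichment is a ratio of the peak to a background that is not given in the sources used here, and it was used only to describe, rank or divide peaks within 1 list. The deposited −log10 p and −log10 q values measure each peak against that background, and the smallest −log10 q values of the 5 lists, 1.30 to 1.33, lie just above the value of a q of 0.05. The deposited score was 10 times the −log10 q value at 99.99% of Pol II peaks and 100% of the peaks of the other lists, and it was not used. Per the files deposited by the authors, the other column used was the position of the summit within the peak. Peaks were called per sample and no pooling is stated. No peaks overlapped within a list. Peak ends were compared with the chromosome lengths of 3 builds: peaks passed the end of 0 of 24 chromosomes in hg19, 20 in hg18 and 15 in hg38. Neither total reads nor reads per peak were analysed here, so the depth of each library is unknown, and no interval allows for it.

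Peaks on chromosomes 1 to 22 and X were compared. A peak was shared when a peak of the other list overlapped it by at least 1 bp, and each share was given a 95% Wilson interval. Chance overlap was measured with 1000 rotations of the first list, with 1 random shift per chromosome and with stretches of over 1 Mb without any peak shortened to 1 Mb, and the p-value is the one-sided share of rotations with as high an overlap. Rotation keeps the spacing and width of peaks but not their position relative to genes or open chromatin, so a share above the rotated one does not separate contact between 2 factors from a common preference for active regions. Associations within Pol II peaks were measured as Mantel-Haenszel odds ratios over 10 strata of Pol II fold enrichment, with 1000 two-sided permutations of a label within strata. Median fold enrichments of shared and unshared peaks within 1 list were compared with 100000 two-sided permutations of the overlap label. Summit distances ran from each overlapped peak of the first list to the nearest summit of the other list. That summit need not belong to the overlapping peak. Distances were given as medians with order-statistic intervals. These tests, the samples in them, the alternatives and the rule for named sites were fixed before the data were examined.

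Shares of OGA peaks were compared with each other by exact McNemar tests on the same OGA peaks, with Benjamini-Hochberg adjustment over 6 tests. These tests, the division of lists into deciles, the exact sign tests of summit distance at sites of all 5 factors, the odds ratios with strata also split by SPT5 or TRIM28, the lists shortened to the length of the O-GlcNAc list, the leaving out of chromosome X, the highest decile of OGA peaks and the stricter threshold for medians were chosen after seeing the data. The alternatives fixed beforehand were a −log10 q of at least 5, an overlap of 50% of the shorter peak, summits within 250 bp, lists shortened to the 2561 strongest peaks by −log10 p, random placement of peaks, all sequences in the lists, strata of Pol II width or none, and merging of peaks within 500 bp. The reference table of genes was of another build (GRCh38), and coordinates were not converted between builds. The planned shares of peaks at promoters, distances from transcription start sites, gene lists and rotation among promoters were therefore not run. Sites are named by the rule fixed for that case: the 5 highest OGA peaks by fold enrichment, the 3 highest of each other list, and the 5 sites with all 5 factors that rank highest by OGA fold enrichment.

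The calculations were tested on simulated data. Of 100 pairs of independent lists made from the 19889 Pol II peaks and rotated TRIM28 peaks, a share of 0.07 had a p-value under 0.05. Planted overlaps of 11.6% and 41.0% of Pol II peaks were recovered as 11.6% and 41.0%. Simulated odds ratios of OGA and TRIM28 within Pol II peaks of 1, 3 and 10 were recovered as 1.04, 3.01 and 9.75. The count of OGA peaks overlapping TRIM28 was 2305 by both the code used here and bedtools 2.31.1. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with GenomeInfoDb 1.38.1 gave the chromosome lengths.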

Results

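The positions of 5 targets on chromatin were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in BJAB cells, an established human B-cell line derived from a Burkitt's lymphoma. RNA polymerase II (Pol II) was precipitated with an antibody to the repeats of its largest subunit. SPT5 is a subunit of the DSIF complex, which takes part in holding Pol II in the promoter-proximal pause and later travels with the elongating polymerase. TRIM28, also called TIF1b or KAP1, is a co-repressor that KRAB zinc finger proteins bring to DNA, and the series title names it beside SPT5 as a pausing factor. O-GlcNAcase (OGA) is the enzyme that removes the sugar O-GlcNAc from serines and threonines of nuclear and cytoplasmic proteins, and the last antibody recognises proteins that carry this sugar. Each target had 1 library and 1 peak list, with no replicates, so the intervals and p-values below describe these lists and cover counting error only. The mouse and rabbit IgG libraries of the series were not analysed here.

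SPT5 and TRIM28 had the longest lists, and OGA had by far the shortest. On chromosomes 1 to 22 and X the lists held 56040 SPT5, 45003 TRIM28, 19889 Pol II, 9251 O-GlcNAc and 2561 OGA peaks. SPT5 and Pol II formed the broadest domains: 16.3% of SPT5 peaks and 11.5% of Pol II peaks were wider than 1 kb, against 0.680% of TRIM28, 0.586% of OGA and 1.19% of O-GlcNAc peaks. The widest SPT5 peak spanned 27057 bp. SPT5 peaks covered 37.5 Mb, TRIM28 peaks 15.6 Mb, Pol II peaks 12.04 Mb, O-GlcNAc peaks 3.78 Mb and OGA peaks 0.719 Mb. The number of reads behind each list is unknown, and a shallower library would give a shorter list.

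The series title concerns the coupling of OGA to SPT5, TRIM28 and Pol II, which was addressed here only by the overlap of OGA peaks with the other lists. TRIM28 peaks overlapped 90.0% of the OGA peaks (2305 of 2561, 95% Wilson interval 88.8% to 91.1%), and SPT5 peaks overlapped 71.9% (1842 peaks, 70.2% to 73.6%). Pol II peaks overlapped 46.2% (1182 peaks, 44.2% to 48.1%), and O-GlcNAc peaks overlapped 24.1% (618 peaks, 22.5% to 25.8%). When the OGA peaks were rotated along their chromosomes, the mean overlap was 1.21% with TRIM28, 2.40% with SPT5, 0.787% with Pol II and 0.317% with O-GlcNAc. The observed shares were therefore 74.2, 30.0, 58.6 and 76.0 times the rotated ones. None of the 1000 rotations reached the observed share for any of the 4 factors (permutation by rotation, one-sided p = 0.001 each, the smallest that it can give). OGA peaks with TRIM28 and no SPT5 numbered 578, against 115 with SPT5 and no TRIM28 (two-sided exact McNemar test, p = 4.4e-75, adjusted over 6 tests 4.4e-75). The order of the shares turned at the shortest length: with every list shortened to its 2561 strongest peaks, SPT5 overlapped 13.2% of OGA peaks, O-GlcNAc 10.5%, Pol II 10.4% and TRIM28 5.82%, which was 52.5, 91.5, 73.8 and 71.6 times the rotated means. With the other lists shortened to the 9251 strongest peaks and all OGA peaks kept, the shares were 39.6% for TRIM28, 34.3% for SPT5, 29.3% for Pol II and 24.1% for O-GlcNAc, so that the order of the full lists did not turn, and they stood at 138, 45.5, 64.1 and 75.6 times the rotated means. A −log10 q of at least 5 in all lists gave 80.2% for TRIM28, 64.2% for SPT5, 40.8% for Pol II and 25.0% for O-GlcNAc. Median fold enrichments of OGA peaks with and without an overlap were 3.30 and 3.96 for TRIM28 and 3.19 and 3.95 for SPT5. They were 3.11 and 3.61 for Pol II (two-sided label permutations, p = 1e-05 for each of these factors, the smallest possible). For O-GlcNAc they were 3.32 and 3.36 (permutation p = 0.416).

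**Figure D1:**
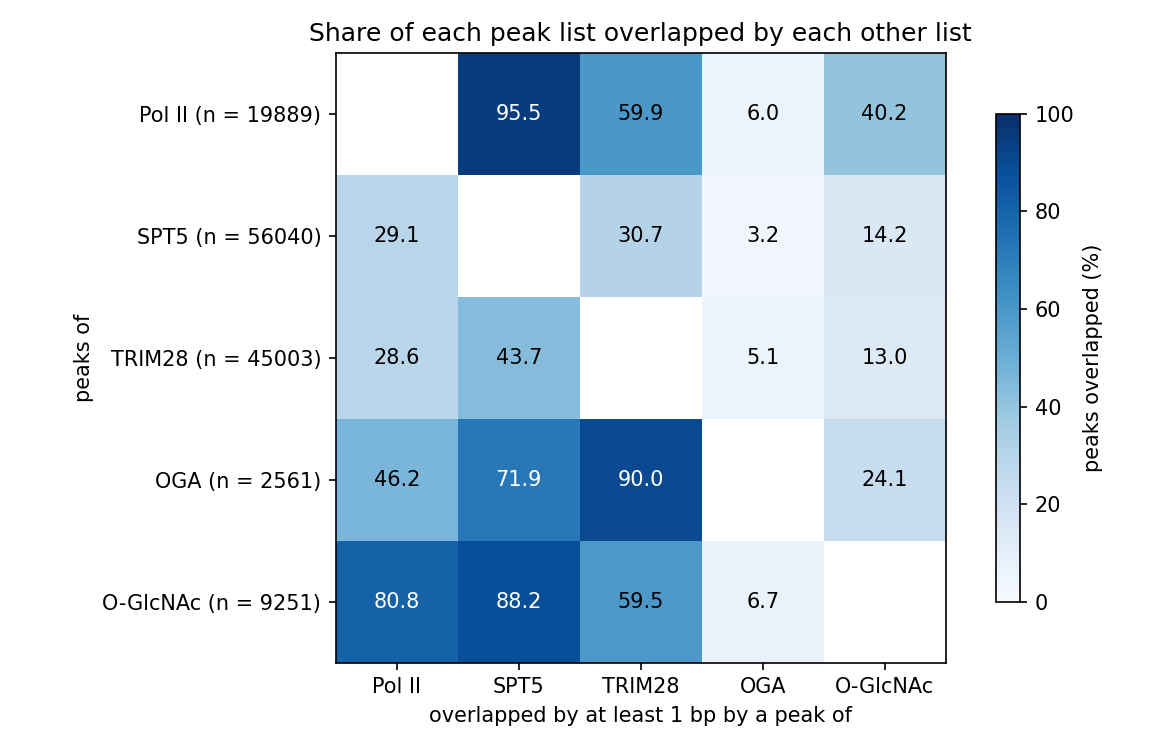
Percent of the peaks of each list (vertical axis, with the number of peaks) that were overlapped by at least 1 bp by a peak of each other list (horizontal axis). In the OGA line TRIM28 reached 90.0% and SPT5 71.9%, and in the Pol II line SPT5 reached 95.5%, while OGA lay at 6.03% of Pol II peaks.

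Sites of OGA fell mostly into 4 combinations. Pol II, SPT5 and TRIM28 together were present at 1104 OGA peaks (43.1%), and 512 of these (20.0% of all OGA peaks) also carried O-GlcNAc. SPT5 and TRIM28 without Pol II or O-GlcNAc were present at 596 OGA peaks (23.3%), and TRIM28 alone at 556 (21.7%). Only 67 OGA peaks (2.62%) had Pol II without TRIM28, whereas 1190 (46.5%) had TRIM28 without Pol II (exact McNemar test, p = 1.8e-266, adjusted 3.5e-266). No peak of another list overlapped 124 OGA peaks (4.84%, interval 4.08% to 5.74%).

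Within Pol II peaks, the presence of OGA went with both TRIM28 and SPT5, and the odds ratio was the higher with TRIM28, with intervals apart at the authors' threshold and an overlap of 1 bp. OGA peaks lay at 9.54% of the 11744 Pol II peaks with both SPT5 and TRIM28 (interval 9.02% to 10.1%) and at 0.924% of the 7248 with SPT5 and no TRIM28 (0.729% to 1.17%). Of the 173 Pol II peaks with TRIM28 and no SPT5, 11 carried OGA (6.36%, 3.59% to 11.0%), and of the 724 with neither factor, 1 did (0.138%, 0.0244% to 0.778%). Seen from the other side, 94.3% of the 1199 Pol II peaks with OGA had TRIM28, against 57.7% of the 18690 without OGA. To hold the height of the Pol II peak fixed, the association was computed within 10 strata of Pol II fold enrichment. The Mantel-Haenszel odds ratio of OGA and TRIM28 was 10.6 (95% interval 8.33 to 13.6), and that of OGA and SPT5 was 4.04 (2.27 to 7.20), each with p = 0.001 over 1000 two-sided label permutations, the smallest they can give. With the strata also split by TRIM28, the odds ratio of OGA and SPT5 was 1.88 (1.04 to 3.39, permutation p = 0.042), whereas that of OGA and TRIM28 split by SPT5 was 10.2 (7.95 to 13.0). SPT5 was missing from 897 Pol II peaks, 12 of them with OGA, which limits the precision of its odds ratio. With a −log10 q value of at least 5 required in all lists, the odds ratio of OGA and TRIM28 was 5.13 (4.22 to 6.23) and that of OGA and SPT5 was 4.38 (2.06 to 9.31), so that their intervals overlapped. They also overlapped when an overlap of 50% of the shorter peak was required, at 8.58 (6.85 to 10.75) with TRIM28 and 4.57 (2.43 to 8.59) with SPT5.

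**Figure D2:**
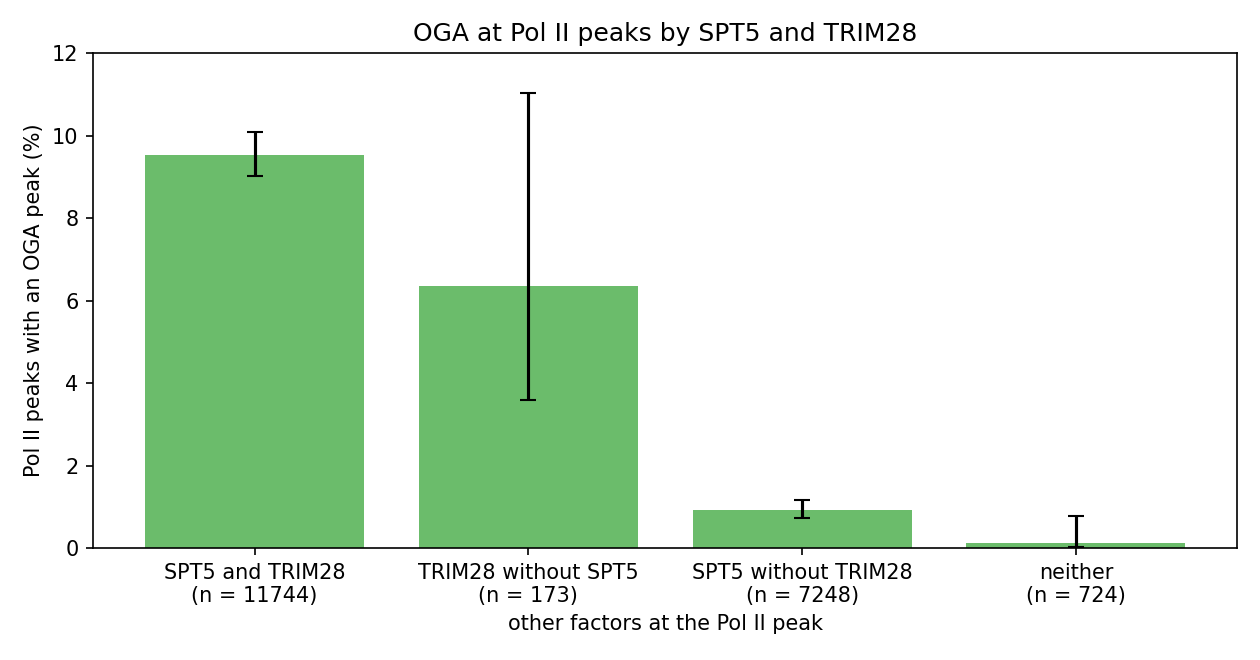
Percent of Pol II peaks overlapped by an OGA peak (vertical axis) in 4 classes of Pol II peaks by overlap with SPT5 and TRIM28 (horizontal axis, with the number of Pol II peaks). Bars are shares and lines 95% Wilson intervals: the share was 9.54% with both factors and 0.924% with SPT5 and no TRIM28.

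The next comparison was between Pol II and the pausing factors themselves. SPT5 was present at 95.5% of Pol II peaks (18992 of 19889), and TRIM28 at 59.9% (11917). Both together were present at 11744 Pol II peaks, and within strata of Pol II height their odds ratio was 4.51 (3.82 to 5.33, permutation p = 0.001, the smallest possible); it was 6.78 without strata and 3.33 (2.81 to 3.95) within strata of Pol II peak width. Pol II peaks with TRIM28 were higher than those without, with median fold enrichments of 5.68 and 4.01 over the authors' background. In the other direction, Pol II peaks overlapped 29.1% of SPT5 peaks (26.9 times the rotated mean) and 28.6% of TRIM28 peaks (36.4 times), and TRIM28 peaks overlapped 30.7% of SPT5 peaks (16.5 times), each with p = 0.001 by permutation of positions in 1000 rotations, the smallest possible.

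SPT5 and TRIM28 differed in how their height went with Pol II. SPT5 peaks with Pol II had a median fold enrichment of 7.19 against 3.01 for those without, while TRIM28 peaks with Pol II had 2.97 against 3.82 for those without (100000 two-sided label permutations within each list, p = 1e-05 each, the smallest they can give). From the lowest to the highest decile of TRIM28 peaks by fold enrichment, the share with SPT5 went from 75.2% to 6.15%, that with Pol II from 52.9% to 2.07% and that with O-GlcNAc from 26.8% to 0.778%. Of the 100 highest TRIM28 peaks, 0 overlapped Pol II (a count of 0 allows up to 3%), 1 overlapped SPT5 and 2 overlapped OGA. Among SPT5 peaks the share with Pol II went the other way, from 4.59% in the lowest decile to 98.6% in the highest. With every list shortened to its 2561 strongest peaks, Pol II overlapped 65.9% of SPT5 peaks but 0.976% of TRIM28 peaks, and TRIM28 overlapped 1.29% of SPT5 peaks.

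**Figure D3:**
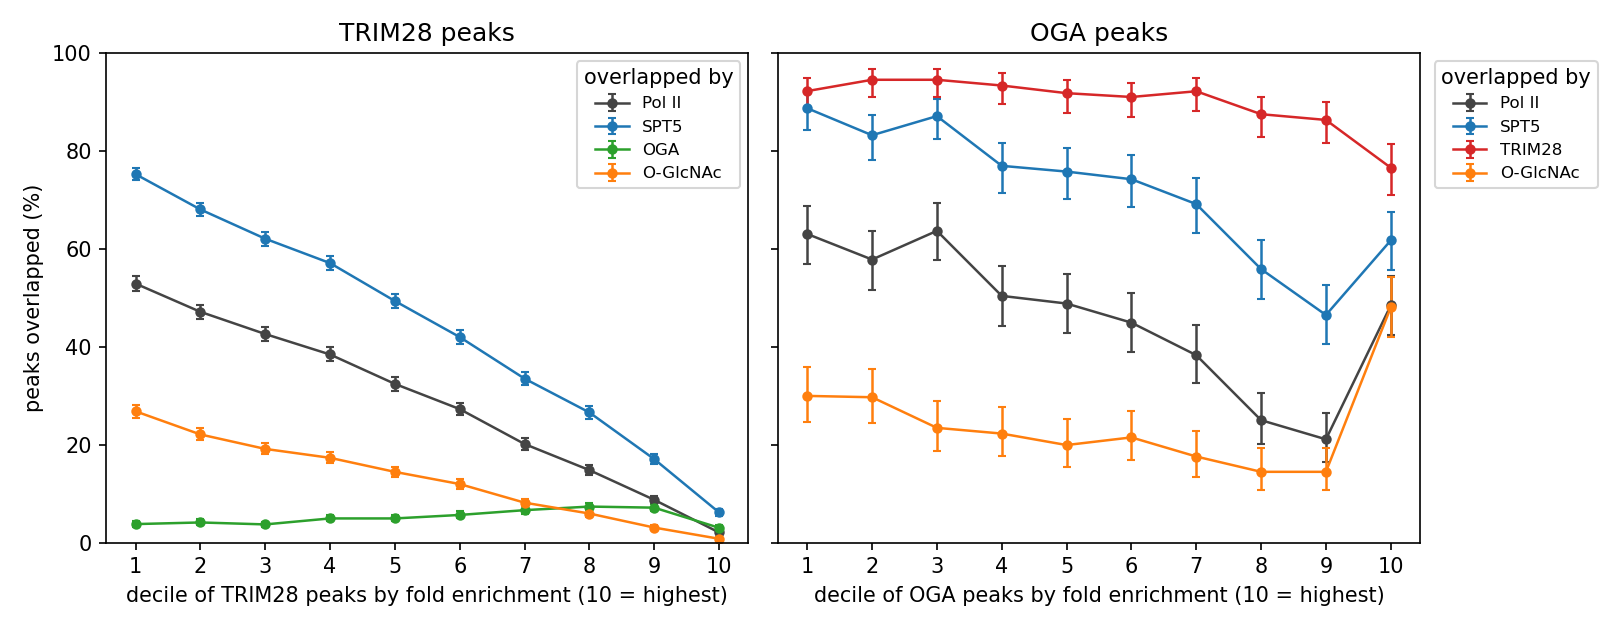
Percent of TRIM28 peaks (left) and OGA peaks (right) overlapped by each other list (vertical axis), by decile of fold enrichment within the list (horizontal axis, 10 being the highest); points are shares and lines 95% Wilson intervals. At TRIM28 peaks the share with SPT5 went from 75.2% to 6.15%, and in the highest decile of OGA peaks the share with O-GlcNAc was 48.0%.

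O-GlcNAc peaks lay mostly at Pol II sites that also carried SPT5. Pol II peaks overlapped 80.8% of the 9251 O-GlcNAc peaks (interval 80.0% to 81.6%), SPT5 peaks 88.2% (87.5% to 88.8%) and TRIM28 peaks 59.5% (58.5% to 60.5%), which was 84.3, 31.4 and 39.9 times the rotated means (permutation by rotation, p = 0.001 each, the smallest possible). The Pol II peaks with O-GlcNAc were the higher ones, with a median fold enrichment of 6.49 against 3.92 for those without (permutation p = 1e-05, the smallest possible). O-GlcNAc peaks lay at 42.0% of the 18992 Pol II peaks with SPT5 and at 20 of the 897 without (2.23%). Within strata of Pol II height the odds ratio of O-GlcNAc was 16.9 with SPT5 (10.9 to 26.2), 1.33 with TRIM28 (1.24 to 1.42) and 1.34 with OGA (1.18 to 1.53), each with permutation p = 0.001, the smallest possible. The odds ratio with SPT5 was 31.8 without strata and 35.4 (17.8 to 70.6) when an overlap of 50% of the shorter peak was required. It was 14.8 with a −log10 q of at least 5, 15.0 within strata of Pol II peak width and 16.0 with strata also split by TRIM28. With every list shortened to its 2561 strongest peaks, Pol II overlapped 18.3% of O-GlcNAc peaks, SPT5 21.6% and TRIM28 0.859%.

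Where peaks overlapped, SPT5 summits lay closest to Pol II and OGA summits closest to TRIM28. The median distance from SPT5 summits to the nearest Pol II summit was 24 bp (95% interval of the median 24 to 25 bp, 16318 SPT5 peaks). That from OGA summits to the nearest TRIM28 summit was 42 bp (40 to 45 bp, 2305 OGA peaks). OGA summits lay a median of 69 bp from O-GlcNAc summits, 105 bp from SPT5 summits and 136 bp from Pol II summits. O-GlcNAc summits stood apart from Pol II by a median of 156 bp (154 to 158 bp), with 8.32% of them within 50 bp. At the 512 OGA peaks that overlapped all 4 other lists, the nearest TRIM28 summit was closer than the nearest Pol II summit at 367 and farther at 140 (two-sided exact sign test, p = 1.7e-24, adjusted over 3 tests 5.1e-24). It was closer than the nearest SPT5 summit at 361 and farther at 149 (exact p = 2.4e-21, adjusted 3.7e-21), and closer than the nearest O-GlcNAc summit at 273 and farther at 235 (p = 0.101, adjusted 0.101). Peak width limits how far apart overlapping summits can lie. At sites of all 5 factors the median widths were 506 bp for TRIM28, 478 bp for O-GlcNAc, 800 bp for Pol II and 1296 bp for SPT5. Pol II and SPT5, which lay farther than TRIM28, were thus also wider. O-GlcNAc was narrower than TRIM28, and its summits lay a median of 73.5 bp away, against 53 bp for TRIM28.

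**Figure D4:**
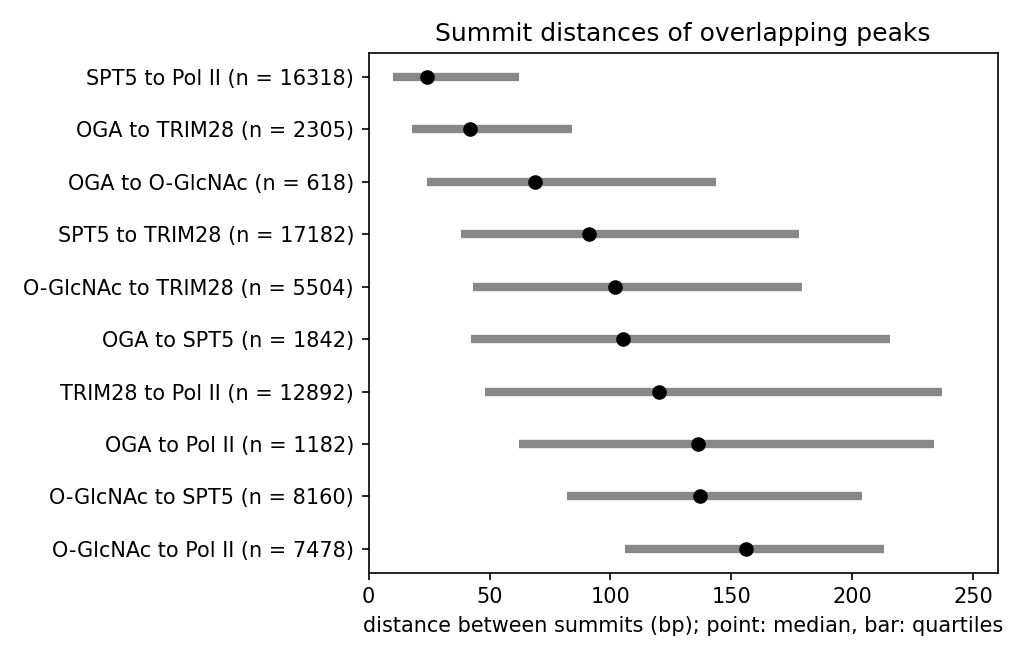
Distance in bp from the summit of each overlapped peak of the first list to the nearest summit of the second (horizontal axis). The vertical axis shows the 10 pairs of lists, with the number of overlapped peaks. Points are medians and bars run from the lower to the upper quartile. SPT5 and Pol II had the smallest median, 24 bp, and O-GlcNAc and Pol II the largest, 156 bp.

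Individual sites are given by position in hg19, since no gene annotation of that build was used here. The highest OGA peaks lay at chromosome X, 2546936 to 2550844 (fold enrichment 35.9), X, 2243013 to 2243596 (34.9), X, 950596 to 951139 (28.7), chromosome 17, 65422 to 66250 (26.0), and chromosome 16, 12416527 to 12417405 (20.9). Of these 5, only the peak at X, 2243013 overlapped all 4 other factors, and the peak at X, 950596 overlapped none. The 3 highest Pol II peaks, at X, 16789345 to 16790231 (41.5), chromosome 6, 111408288 to 111409098 (27.2), and chromosome 1, 144310765 to 144311994 (25.9), all carried SPT5 and no other factor. All 3 of the highest SPT5 peaks carried Pol II, at chromosome 11, 118963689 to 118966730 (28.1), chromosome 17, 4242909 to 4246294 (28.0), and X, 153685949 to 153686959 (25.7). The 3 highest TRIM28 peaks, at chromosome 1, 2787708 to 2788301 (45.4), chromosome 15, 80207993 to 80208683 (37.8), and chromosome 4, 6060132 to 6060796 (35.7), overlapped no other list. All 3 of the highest O-GlcNAc peaks lay on chromosome 19, at 6199405 to 6199984 (18.5), 8617586 to 8618026 (17.8) and 35167873 to 35168607 (17.3), and the first and last of them carried Pol II and SPT5.

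Among the sites held by all 5 factors, the highest by OGA after X, 2243013 were chromosome 19, 41869838 to 41870643 (OGA fold enrichment 20.0), chromosome 17, 1359319 to 1359910 (19.7), chromosome 11, 45376591 to 45377241 (19.6), and chromosome 19, 49954647 to 49955524 (19.4). At chromosome 19, 41869838 the overlapping peaks had fold enrichments of 5.35 for Pol II, 9.40 for SPT5, 2.76 for TRIM28 and 5.56 for O-GlcNAc, each within its own list. Within 20 kb of its summit on either side lay 2 Pol II, 5 SPT5, 4 TRIM28, 1 OGA and 2 O-GlcNAc peaks. The higher of the 2 Pol II peaks there, at 41859505 to 41860181 (14.7), had SPT5, TRIM28 and O-GlcNAc peaks but no OGA peak.

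**Figure D5:**
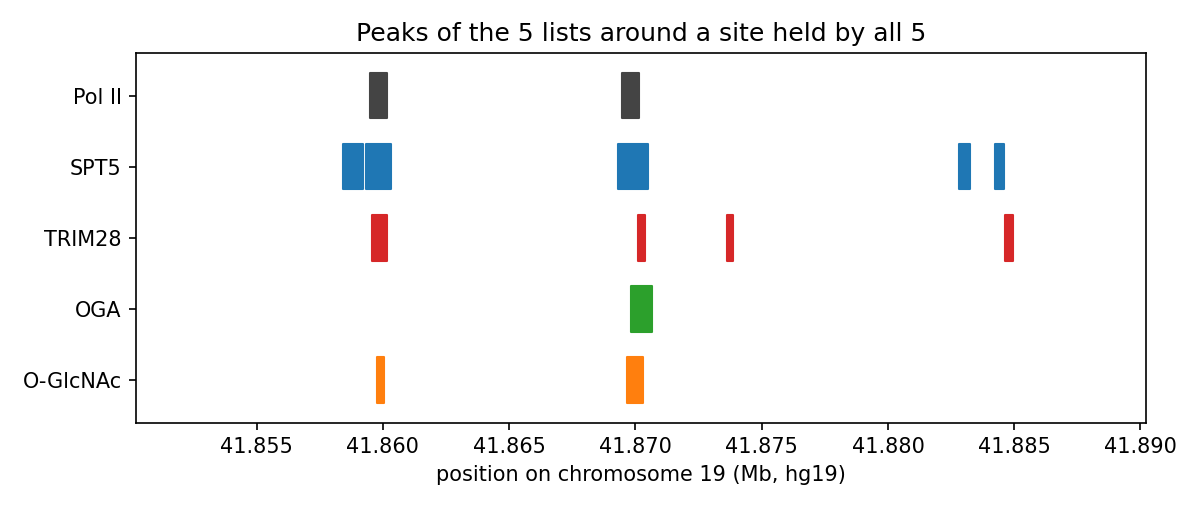
Peaks of the 5 lists (vertical axis) within 20 kb of an OGA summit on chromosome 19 (horizontal axis, position in Mb, hg19); each box runs from the start to the end of a peak. The OGA peak at 41869838 to 41870643 overlaps peaks of all 4 other factors, and the Pol II peak at 41859505 to 41860181 has no OGA peak.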

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

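Both tests in this part were chosen only after the result was seen. Peaks outside the chromosomes compared stood out because the main comparisons left them out, and they entered only the alternative with all sequences in the lists. The lists held 63 SPT5, 41 TRIM28, 19 Pol II, 14 O-GlcNAc and 6 OGA peaks on chromosome Y. The mitochondrial genome held 5 O-GlcNAc peaks, which had fold enrichments of 1.32 to 1.33, and 1 SPT5 peak from base 5 to base 16566 with a fold enrichment of 1.61.

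Of the 10 highest OGA peaks, 4 lay at the start of chromosome X, between 0.951 and 3.06 Mb. Of the 6 OGA peaks on Y, 5 had a partner on X at the same offset of 50000 bp, and 3 of the 4 high OGA peaks on X had a partner on Y. Sequence that is the same on X and Y gives such a partner whether or not the site is bound, so these partners do not decide how the peaks arose. Of these 4, 1 overlapped peaks of all 4 other lists, and 1 overlapped no other list. This does not decide whether regions high in every library were the cause. The control and depth behind each list are unknown, and such a region need not be called as a peak. Whether OGA itself binds there stays open, since the IgG libraries were not analysed here, and no biological explanation was tested.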

How the results depend on the processing

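The alternatives without X, with the highest decile of OGA peaks, with lists at the O-GlcNAc length, with strata split by another factor, and with a stricter threshold for medians were chosen after seeing the data. All 72 alternatives for the 10 shares of overlap stayed above rotation with permutation p = 0.001, the smallest possible, at 5.30 to 206 times the rotated mean, and all 29 alternatives for the 6 odds ratios kept their direction and their side of the threshold. The odds ratio of OGA and TRIM28 ranged from 5.13 to 12.2, that of OGA and SPT5 from 1.88 to 4.92 and that of OGA and O-GlcNAc from 1.23 to 1.87. With a −log10 q of at least 5, 1663 OGA peaks were left by construction, and median summit distances became 156 bp for OGA and Pol II, 116 bp for OGA and SPT5, 38 bp for OGA and TRIM28, 56 bp for OGA and O-GlcNAc, 22 bp for SPT5 and Pol II and 99 bp for SPT5 and TRIM28; the cause was not tested. At the same threshold 3 differences in median fold enrichment turned: TRIM28 peaks with minus without OGA went from 0.249 to -0.0806 (permutation p = 0.070), and O-GlcNAc peaks went from 0.225 to -0.0493 with minus without Pol II (p = 0.40) and from 0.127 to -0.0407 with minus without SPT5 (p = 0.565); the cause was not tested. Another 16 of the 20 kept their direction and side, and O-GlcNAc peaks with minus without TRIM28 passed the threshold, from -0.0416 (p = 0.334) to -0.157 (permutation p = 2e-04). The order of TRIM28 and SPT5 at OGA peaks turned only when all lists were shortened to 2561 peaks. Shares of peaks at promoters, gene lists and rotation among promoters were not run, since no annotation of hg19 was used here. Unknown read depth limits all absences: a peak missing from the OGA list may lie below its threshold, and with the 2561 strongest peaks of each list TRIM28 overlapped 5.82% of OGA peaks.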

Other observations

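The odds ratio of OGA and TRIM28 and the comparisons of median fold enrichment with and without 1 other factor were fixed beforehand, and the test of OGA peaks with TRIM28 alone near Pol II was fixed before its result was seen. The other tests in this part, and the use of the odds ratio against Pol II height, were chosen only after the result was seen. SPT5 peaks without any other factor numbered 33039 (59.0% of the list), and 45.5% of them had a Pol II summit within 10 kb, against at most 14.2% in 1000 rotations (permutation p = 0.001, the smallest possible). TRIM28 peaks without any other factor numbered 24503 (54.4%), and 19.1% of them had a Pol II summit within 10 kb, against at most 11.5% in the rotations (permutation p = 0.001, the smallest possible). OGA peaks with TRIM28 alone did not pass this test: 12.2% of the 556 had a Pol II summit within 10 kb. That was inside the range of the rotations, which reached 15.5% (permutation p = 0.179). The nearest Pol II summit lay a median of 66.6 kb away. These OGA peaks were picked for lying outside the Pol II, SPT5 and O-GlcNAc lists, a limit that the rotated peaks did not share. The test therefore cannot show that such OGA sites avoid the surroundings of Pol II. Of all 680 OGA peaks outside the Pol II, SPT5 and O-GlcNAc lists, 81.8% overlapped TRIM28, against at most 2.35% in the rotations.

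Chromosome 19, which made up 2.06% of the span compared, held 9.86% of O-GlcNAc, 7.0% of Pol II, 6.20% of SPT5, 6.13% of OGA and 4.71% of TRIM28 peaks. Of the TRIM28 peaks without any other factor, 3.26% lay there. The highest decile of OGA peaks by fold enrichment differed from the decile next to it in all 4 shares, with intervals apart: the share with O-GlcNAc was 48.0% against 14.5%, that with Pol II 48.4% against 21.1% and that with SPT5 61.7% against 46.5%. The share with TRIM28 was lower, 76.6% against 86.3%. Of the 100 highest OGA peaks, 75 overlapped O-GlcNAc, 72 TRIM28, 67 SPT5 and 64 Pol II. From the lowest to the ninth decile the share with O-GlcNAc had gone down from 30.0%, that with Pol II from 63.0% and that with SPT5 from 88.7%. For Pol II and SPT5 the share in the highest decile thus stayed below that in the lowest. Over the whole list OGA peaks with and without O-GlcNAc had median fold enrichments of 3.32 and 3.36 (permutation p = 0.416). Within strata of Pol II height and TRIM28, the odds ratio of OGA and O-GlcNAc was 1.23 (1.08 to 1.40, permutation p = 0.005), which does not show whether OGA lowers O-GlcNAc where it is bound, since an enzyme that goes to its substrate would also give a value above 1.

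Of the Pol II peaks with OGA, 94.3% carried TRIM28. Pol II height as the whole cause was argued against by the odds ratio of 10.6 (8.33 to 13.6) within strata of Pol II height. TRIM28 material carried over into the OGA library would put OGA at the highest TRIM28 peaks. The share with OGA did rise from 3.78% in the lowest decile of TRIM28 peaks to 7.36% in the eighth. It was 3.02% in the highest. Over the TRIM28 list this argues against carry-over as the whole cause of OGA at TRIM28 peaks. Pol II overlapped only 2.07% of that highest decile, so the fall says little about Pol II sites. Among TRIM28 peaks with Pol II and SPT5, those with OGA were the higher ones. Their median fold enrichments with and without OGA were 3.68 and 2.97 outside the O-GlcNAc list, and 3.36 and 2.88 within it. Carry-over at Pol II sites thus stays open. Background common to all 5 libraries could not be decided. O-GlcNAc peaks overlapped 49.2% (46.3% to 52.1%) of the 1131 Pol II peaks with OGA and TRIM28, near the 46.5% of all Pol II peaks with TRIM28. SPT5 peaks overlapped 1120 of the 1131, but also 11744 (98.5%) of all 11917 Pol II peaks with TRIM28. Background need not pass the threshold of each list, so absence from the O-GlcNAc list does not decide the question. Background common to OGA and TRIM28 alone also stays open, since the IgG libraries were not analysed here. The joint presence of both proteins stays open as a hypothesis, and no biological explanation was tested.

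The highest TRIM28 peaks lacked Pol II and SPT5: 6.15% of the highest decile (5.49% to 6.89%) overlapped SPT5, against 47.9% of the rest. TRIM28 peaks without any other factor had a median fold enrichment of 4.05, against 3.04 for those with another. Whether regions high in every library explain this cannot be told from the overlap with SPT5, which restates the pattern. No other explanation was tested, since neither an annotation of hg19 nor the IgG libraries were used here.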
